A study of Caenorhabditis elegans with 45 samples.

How the data were processed

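The series measured polyadenylated RNA from whole worms of Caenorhabditis elegans in 45 libraries, 1 per time point, in 3 courses: 16 of continuous N2, 22 of N2 dauer exit and 7 of glp-4(bn2). Per the labels' protocols, worms were grown on agar plates with the food bacterium OP50, RNA was isolated with Tri-reagent and libraries were made with a stranded mRNA kit. Courses and hours were taken from the sample titles. Replicate numbers within a course only name libraries in accession order.

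The main table held raw read counts per gene as deposited by the authors, with whole numbers for 20182 genes and 45 libraries; the aligner, the counting tool, the annotation and the genome build are not given in the sources used here. A second table deposited by the authors held log2 values. Checked against the counts, every value equalled log2 of the count divided by its library total, times the mean total of its course, plus 8, to 4 decimals, so the authors' scaling used library size alone and each course separately. Gene symbols came from a names table matched on the gene identifier, which 18778 identifiers (93.0%) did; 3 rows had identifiers of another form. Coordinates are those of build WBcel235, the reference annotation used here, and the build behind the counts may differ. How reads shared by near-identical genes were assigned is not given in the sources used here, so single members of the col, major sperm protein, abu and vitellogenin families are uncertain where copies are alike.

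Counts were tested with edgeR 4.0.16 in R 4.3.3, with its filter on low counts, TMM factors and the quasi-likelihood F-test, separately for each course. The oscillation model had an intercept, a linear term in the hour, and the cosine and sine of an 8 h period, which were tested together with 2 degrees of freedom. A gene was called oscillating at a Benjamini-Hochberg adjusted p under 0.05 and a fitted amplitude of at least 0.5, on the log2 scale from mean to peak. Peak times came from the cosine and sine coefficients, with standard errors by the delta method. The period of 8 h is a general value for larval cycles, which depend on temperature; the growth temperature of the courses is not given in the sources used here, so a course may have another cycle length, and counts were repeated for periods from 5 to 12 h in steps of 0.5 h. In dauer exit the wave was fitted to hours 11 to 22, because the first hours of recovery are not linear. The linear term of the same model gave rising and falling genes in continuous N2 and glp-4, at an adjusted p under 0.05 and a fitted change over the course of at least 1 on the log2 scale. Over all 22 hours of dauer exit a natural spline with 3 degrees of freedom was tested, and direction came from the fitted change between the first and last hour. Fitted values used edgeR's prior count of 0.125, so fitted changes of genes near 0 depend on it, and observed CPM are given for such genes. CPM was computed from the total counts of the library, and means of the first and last 3 libraries of a course are given with their SD. CPM and fitted changes are relative to the other RNA of whole worms and do not give levels per cell or per tissue. Where a gene had no counts in 3 libraries, the floor was 3 counts over the 3 libraries, which covers counting error only.

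The courses were compared by the overlap of called genes, by the circular mean of the difference in peak time, and by joint edgeR fits with a course-specific wave tested against one shared wave on a shifted clock. For glp-4 the shift could not be taken from genes called in both courses, as planned, because there were none, so each whole-hour shift from 0 to 7 h was tried, a choice made after seeing the data. Since simulated data then gave false calls there, limma 3.58.1 (voom with one spread per course) was added after seeing the data. Germline levels were compared without a test.

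Before the data were examined, 29 gene lists were fixed from general knowledge of worm biology, covering cuticle collagens, molting, regulators, germline, tissues and basic functions; 10 of their entries had no match in the table. Lists were tested with one-sided Fisher's exact tests against all tested genes, adjusted over 258 tests, and called genes were also counted with p-values adjusted over the list alone. Of the adult cuticle collagens 1 gene, col-19, was tested in each course. Of the dauer cuticle list, which holds collagens and cuticlins, 2 genes were tested in dauer exit, and 1 of them oscillated, also when adjusted over the list alone. Genes named in the text follow a rule fixed before the data were examined: for each oscillation or trend the 8 called genes with a symbol and the largest amplitude or change (5 for falling genes), the 3 largest called members of each list with at least 3 called, 21 fixed genes, and the 5 genes with the smallest adjusted p of each interaction. The members of furrow and other lists named as ends of a range, and pairs of a list chosen as examples, come from those genes.

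Total counts were 18512549 to 43984242 per library, and counting error was small beside the scatter of libraries for most named genes. The fits were tested on simulated data drawn from the real means and library sizes, with 50 genes changed at each size. Simulated counts were independent between genes and libraries, with flat levels for unchanged genes and waves of exactly 8 h. Real libraries differ in these respects, so false calls may be more frequent and recovery lower in the real data. Of waves with amplitudes 0.5, 1, 1.5 and 2, the fit recovered 34, 76, 98 and 96% in continuous N2 (6 false calls among 15622 genes), 18, 56, 82 and 92% in dauer exit (6 among 15360), and 0, 2, 28 and 58% in glp-4 (4 among 14407). Of linear changes of 1, 2, 3 and 4 it recovered 30, 80, 92 and 100% in continuous N2 and 0, 10, 64 and 88% in glp-4, and of spline changes 24, 82, 98 and 100% in dauer exit. Of wave differences of 0.5, 1, 1.5 and 2 between N2 courses it recovered 24, 74, 80 and 98%, with 10 false calls among 15207 genes, and between continuous N2 and glp-4 it gave 204 false calls among 14022 genes, against 25 by voom.

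Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, limma on the authors' log2 table, an adjusted p under 0.01, an amplitude of 1, periods of 7 and 9 h, a quadratic or no trend, other hours or a spline of 4 degrees of freedom in dauer exit, clock shifts of 1 h more or less, and each library left out in turn. Added after seeing the data were library size as the only scaling, periods of 10 and 12 h in glp-4, courses without hours 34 to 36 or without hours 50 and 52, and the separate spread per course. Random orders of libraries within a course, and random splits of the libraries of 2 courses, were drawn 40 times each, the real one included; splits that edgeR could not fit were drawn again.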

Results

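The series held 45 RNA-seq libraries of polyadenylated RNA from whole Caenorhabditis elegans, arranged as 3 time courses of postembryonic development. The first course followed N2, the standard laboratory strain, in continuous development from hatched first-stage larvae put on food, with 16 libraries taken hourly at sample-name hours 21 to 36. Per the labels these worms grew slowly and were in fact 22 to 37 hours into development, and the sample-name hours are used here. In the second course, N2 dauer larvae (a long-lived, stress-resistant diapause stage) were given food and sampled hourly from 1 to 22 hours, giving 22 libraries. The third course followed glp-4(bn2), a temperature-sensitive mutant that lacks most germ cells when grown at the restrictive temperature, with 7 libraries taken every 2 hours from 40 to 52 hours. Total counts per library were 18512549 to 43984242 in continuous N2, 18521397 to 23904100 in dauer exit and 23978316 to 36817376 in glp-4. There was 1 library per time point and no replicate of any time point. The errors below therefore come from the scatter of libraries around fitted curves, and p-values of the fits measure only that scatter. Fisher's exact tests and the permutation of collagen peaks take genes as units instead. Genes measured in the same libraries are not independent, so the p-values of these tests may be too small. No library pair looked like one library deposited again: over 990 pairs, the smallest chi-square per gene, between hours 4 and 5 of dauer exit, was 18.6.

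The first comparison asked which transcripts oscillate during continuous larval development, the subject that the series title names. In N2, genes of the cuticle and of molting rose and fell in an 8 h wave, with peaks at different times for different groups. The molting gene mlt-10 (WBGene00015646; chromosome II, 546705 to 552032, WBcel235) swung between 19.3 and 1185 CPM (the count scaled to the library total), with a fitted amplitude of 3.15 ± 0.07 (SE, log2, from mean to peak) and peaks at 24.0 and 32.0 h. The furrow collagen dpy-7 (WBGene00001069; chromosome X, 7536467 to 7537792), which forms the circumferential furrows of the cuticle, ranged from 4.53 to 828 CPM and peaked at 22.5 and 30.5 h. The period homolog lin-42 (WBGene00018572; chromosome II, 1233236 to 1252359) ranged from 21.3 to 651 CPM, with an amplitude of 1.88 ± 0.16 and a peak at 23.3 h. By contrast, the body-wall myosin gene unc-54 stayed between 5821 and 7696 CPM and its wave did not pass the test (amplitude 0.12 ± 0.04, adjusted p = 0.0507 by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment).

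In all, 4116 of the 15622 genes tested (26.3%) oscillated, with an adjusted p under 0.05 by the same test and an amplitude of at least 0.5. The median amplitude of these genes was 1.05 (quartiles 0.72 and 1.87), and 928 of them had an amplitude of 2 or more. All 6 furrow collagens and all 14 other named cuticle collagens oscillated, whether adjusted over all genes or adjusted over the list alone. Of the col collagens, 102 of 119 did (104 adjusted over the list alone). All 24 genes of molting and the apical matrix oscillated, as did 42 of 46 hedgehog-related genes (44 adjusted over the list alone) and 24 of 32 astacin proteases (25 adjusted over the list alone). The counts were 19 of 26 for patched-related genes, 16 of 18 for pharyngeal cuticle abu and phat genes and 15 of 19 for molting cycle regulators, and these 3 counts did not change when adjusted over the list alone. Each of these lists was enriched among oscillating genes by Fisher's exact test (one-sided, adjusted over 258 tests); the largest adjusted p among them was 0.0021, for the 6 furrow collagens. Seam cell genes, which mark the lateral epidermis, oscillated in 7 of 10 cases and genes of collagen processing and cross-linking in 7 of 10 (8 adjusted over the list alone), each with an adjusted p of 0.0235. Pharynx genes (6 of 9, adjusted p = 0.0625), heterochronic genes (7 of 13, 0.140), vitellogenins (4 of 6, 0.182), dauer and stress resistance genes (10 of 24, 0.271) and intestine genes (7 of 18, 0.56801) were not enriched by that test, and their counts were the same adjusted over the list alone. The 4 called vitellogenins had a median amplitude of 0.26 in the first cycle of the course and 4.35 in the second. The whole list also rose over the course. Their calls therefore do not tell a repeating wave from a single late rise.

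Several groups of genes of other tissues and of basic cell functions had small 8 h waves, whatever their trend over the course. The median fitted amplitude was 0.14 for 20 body-wall muscle genes, 0.15 for 27 neuronal genes, 0.06 for 33 respiratory chain genes and 0.10 for 26 early and meiotic germline genes. Among 80 ribosomal protein genes 1 oscillated by edgeR, and the counts were 1 of 23 for DNA replication and cell cycle, 1 of 27 for oogenesis, 2 of 15 for vulva and egg-laying and 1 of 9 for housekeeping controls. Adjusted over the list alone, the ribosomal and housekeeping genes no longer passed, and the other 3 counts were the same. The control ama-1, which encodes the large subunit of RNA polymerase II, had an amplitude of 0.05 ± 0.04 and an adjusted p of 0.552 (edgeR).

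**Figure D1:**
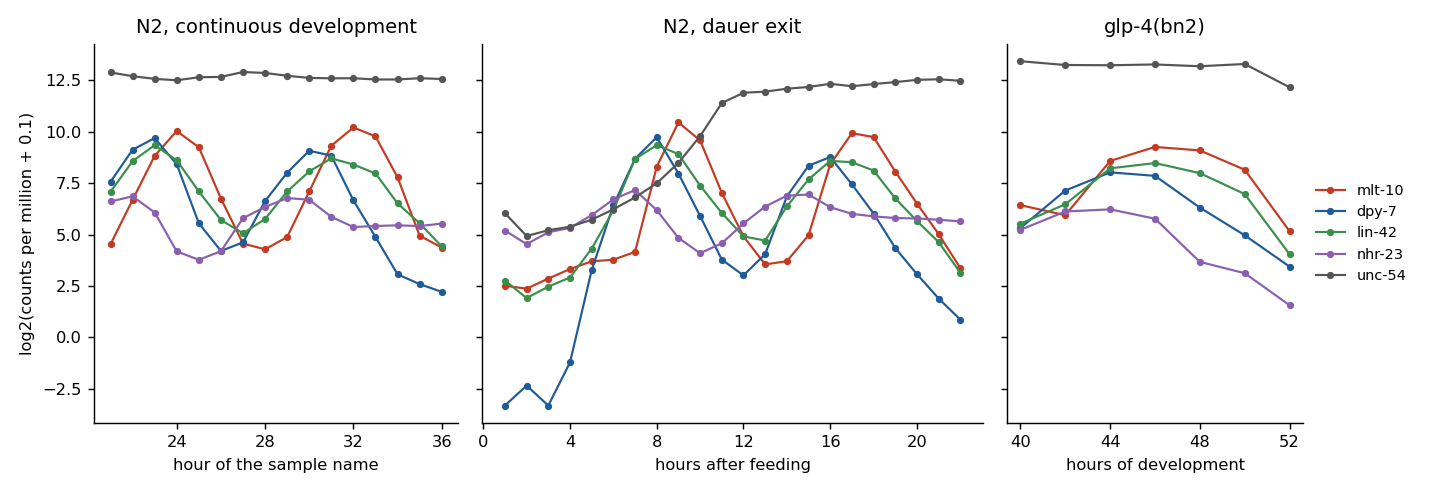
Expression of 5 named genes, as log2 of CPM plus 0.1, against time in each course; each point is 1 library. The molting gene mlt-10 ranges from 19.3 to 1185 CPM in continuous N2, while unc-54 stays between 5821 and 7696 CPM there and climbs in dauer exit.

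Peak times were spread over the cycle, and gene groups peaked at different times. Furrow collagens peaked on average at 22.5 h, between dpy-9 at 22.4 h and dpy-8 at 22.8 h. The other named cuticle collagens peaked on average at 23.7 h, among them lon-3 (amplitude 3.03 ± 0.13, peak at 23.7 h) and rol-6 (2.69 ± 0.14, peak at 24.1 h). Of this list dpy-14 and dpy-17, named after their values were seen, peaked before all furrow collagens, both at 21.5 h. The first fitted peak of bli-1, at 22.5 h, fell within the furrow range but was not an observed one. Its mean was 1.24 CPM at hours 21 to 23, and its highest value in the course was 2282 CPM. The fitted peak of bli-1 still enters the list mean and the test that follows. The mean difference of 1.13 h between the 2 collagen groups had a two-sided exact permutation p of 0.0256 over 38760 arrangements. Molting and apical matrix genes peaked on average at 23.3 h, astacin proteases at 25.8 h and the abu and phat genes at 26.1 h. Among secreted and membrane proteins of the epidermis, the hedgehog-related gene grl-5 (3.51 ± 0.10) peaked at 24.2 h, the warthog gene wrt-2 (3.14 ± 0.20) at 23.1 h and the patched-related gene ptr-16 (3.02 ± 0.14) at 24.6 h. The proteases nas-37 (2.53 ± 0.10), needed to shed the old cuticle, and nas-14 (3.05 ± 0.12) peaked at 23.1 and 24.6 h. Peaks of the col collagens were dispersed (mean resultant length 0.438 around 25.9 h, against 0.995 for furrow collagens), with col-146 (3.78 ± 0.28) peaking at 27.4 h and abu-7 (3.86 ± 0.60) of the pharyngeal cuticle at 26.7 h. Over all oscillating genes the fullest 1 h bin of the cycle held 24.4% of peaks and the emptiest 5.98%.

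**Figure D2:**
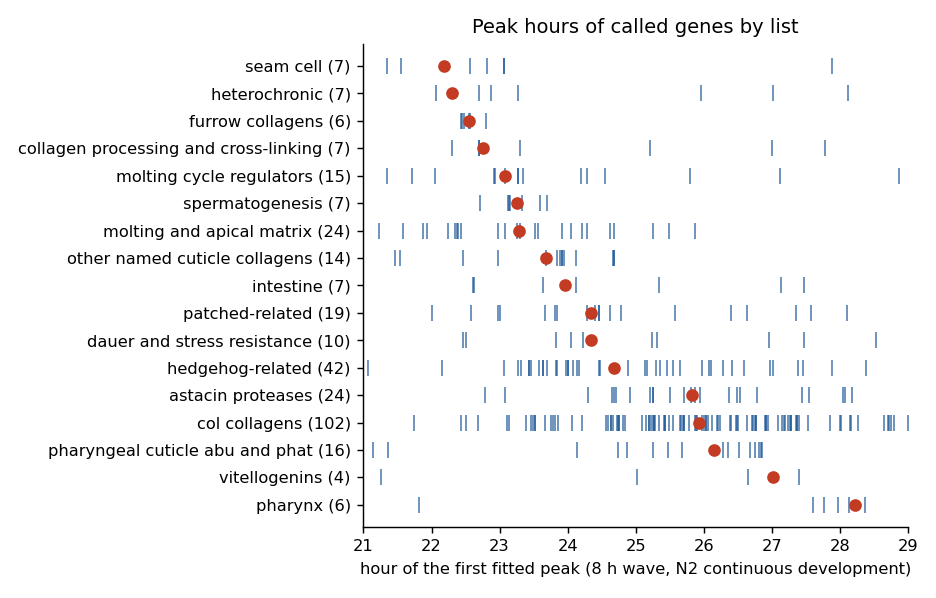
First fitted peak hour of the 8 h wave in continuous N2 of each called gene (ticks) and the circular mean of each list (dots), for lists with at least 3 called genes and their number in parentheses. Furrow collagens cluster around 22.5 h, and the abu and phat genes centre on 26.1 h.

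Regulators oscillated with their own timing. The nuclear receptor nhr-23, which drives molting gene expression, peaked at 21.3 h (amplitude 1.04 ± 0.17), the transcription factor grh-1 at 23.3 h (1.67 ± 0.15), bed-3 at 24.5 h (2.63 ± 0.17) and the nuclear receptor nhr-25 at 25.8 h (1.18 ± 0.13). The zinc finger genes blmp-1 and lin-29 had small waves (0.62 ± 0.17 and 0.71 ± 0.13) that peaked at 22.9 and 22.7 h. The pharyngeal myosin gene myo-2 (0.79 ± 0.05) peaked at 27.6 h. The intestinal marker elt-2 and the heterochronic gene lin-28 did not pass the test (amplitudes 0.08 ± 0.07 and 0.09 ± 0.04).

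The wave repeated within the course. Library profiles over all tested genes with a mean log2 CPM above 0, whether called or not, after removing each gene's linear trend, correlated negatively at a lag of 4 h (mean r across genes −0.67) and positively at 8 and 9 h (0.41 and 0.44). The log2 values of hours 21 to 28 and of hours 29 to 36 were correlated for each gene. Of the 4116 oscillating genes 2340 (56.9%) had r of 0.7 or more, against 21.2% of the 11506 genes not called. The oscillating genes were chosen by their 8 h wave over the same hours, so their share describes them and does not test the repeat. Among called genes, all 6 furrow collagens, 73 of 102 col collagens and 17 of 24 molting and apical matrix genes reached that r. Only 2 of 7 heterochronic genes, 3 of 7 collagen processing genes and 1 of 4 vitellogenins did. The collagen gene bli-1, which was called oscillating, did not (r = -0.49). Counts of called genes were higher at a period of 9 h (4557) than at 8 h (4116). Genes called at 8 h with an amplitude of at least 1 had a median best period of 8.4 h (quartiles 8.1 and 8.8 h). Without a trend term the counts were 2935 at 9 h, 3081 at 8.5 h and 2999 at 8 h.

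**Figure D3:**
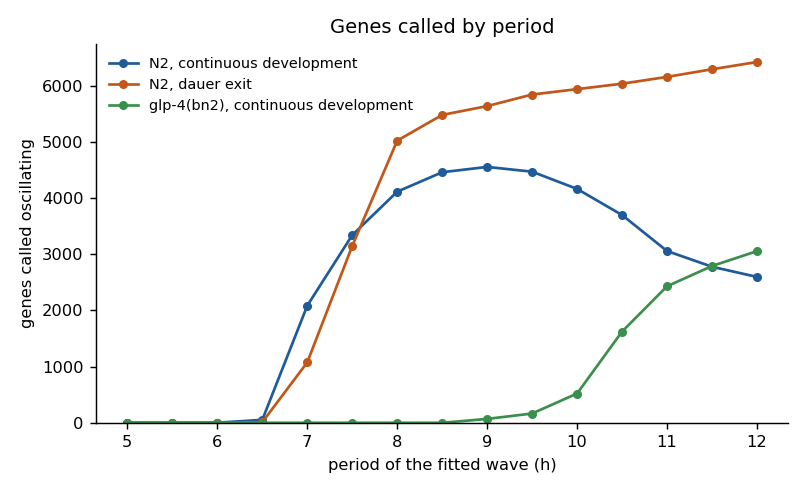
Number of genes called oscillating in each course against the period of the fitted wave. In continuous N2 the count is 4116 at 8 h and 4557 at 9 h; glp-4 reaches 3057 at 12 h.

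A second question of the same course was which transcripts rose or fell steadily while the wave ran. Reproductive and adult genes came on. The yolk protein gene vit-2 climbed from 1.03 ± 0.957 CPM (SD, mean of hours 21 to 23, n = 3) to 5010 ± 3282 CPM (hours 34 to 36), vit-6 from 0.945 to 7070 CPM, and the adult cuticle collagen gene col-19 from 0.201 to 1441 CPM. The major sperm protein gene msp-40 had no counts at hours 21 to 23 and 61.9 CPM at hours 34 to 36, at least 1427.7-fold higher against a floor of 3 counts over the 3 libraries. The meiosis regulator gld-1 rose 8.28-fold, from 39.5 to 327 CPM, and the cyclin gene cyb-1 7.78-fold. In the other direction, the tubulin gene tba-8 fell from 86.1 to 0.0371 CPM and the heterochronic gene hbl-1 from 25.6 to 4.03 CPM.

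With the linear term tested beside the wave, 3219 genes rose and 2394 fell by at least 1 on the log2 scale over the course (edgeR's quasi-likelihood test, adjusted p under 0.05). Rising genes included all 15 major sperm protein genes tested, 42 of 46 spermatogenesis genes, 25 of 27 oogenesis genes, 18 of 26 early and meiotic germline genes, all 6 vitellogenins and 56 of 119 col collagens. Oogenesis examples were puf-5 (2.21 to 63.9 CPM) and the eggshell gene cpg-2 (12.12 to 264 CPM). The germline helicase gene glh-1 rose 2.41-fold. Falling genes included 18 of 27 neuronal genes, 7 of 9 pharynx genes (8 adjusted over the list alone), 7 of 13 heterochronic genes, 8 of 19 molting cycle regulators (6 with RLE size factors and 5 with library size only), 7 of 10 seam cell genes and all 6 furrow collagens. The other counts here were the same adjusted over the list alone. Of the 119 col collagens 19 fell, adjusted over all genes. Among neuronal genes unc-86, a transcription factor of neuronal fate, fell from 7.82 to 2.28 CPM and the acetylcholine transporter gene unc-17 from 15.4 to 5.74 CPM. The nuclear receptors nhr-25 (24.1 to 5.98 CPM) and daf-12 (85.8 to 24.3 CPM), and lin-14 (50.7 to 31.8 CPM), also fell. The median fitted change over all genes was -0.12, and it lay between -0.03 and 0.04 with the other scalings, so falls close to the threshold depend on the scaling more than rises do. Hours 21 to 23 and 34 to 36 fall on different parts of the 8 h wave, so CPM means of oscillating genes at these hours mix wave and trend. Rises and falls are relative to the other RNA of whole worms. A changed share of a tissue is therefore not told apart from a change within its cells.

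The second course asked how gene expression restarts when dauer larvae are fed. Muscle, cuticle and reproductive transcripts came on, and neuronal transcripts fell relative to the other RNA of the worm. Levels per cell were not measured, so a changed share of a tissue cannot be told apart from a change within its cells. The myosin gene myo-3 rose 58.1-fold, from 9.84 ± 4.15 CPM at hours 1 to 3 to 572 ± 86.6 CPM at hours 20 to 22 (SD, n = 3 libraries each), unc-54 rose 133-fold from 44.3 to 5882 CPM, and the 20 body-wall muscle genes together took 0.298% of counts at first and 2.17% at the end. The neuropeptide convertase gene egl-3 fell from 598 to 75.2 CPM and the touch receptor channel gene mec-4 from 11.5 to 1.35 CPM. The cuticle collagen gene col-19 had no counts in the first 3 libraries and 1385 CPM in the last 3, at least 31053-fold higher. Over the 22 hours 13367 of 15977 genes passed the test of a natural spline with 3 degrees of freedom (edgeR's quasi-likelihood F-test, adjusted p under 0.05), and by the fitted change between hour 1 and hour 22, 4778 rose and 3943 fell by at least 1.

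Body-wall muscle genes rose in 16 of 20 cases, col collagens in 110 of 121, oogenesis genes in 26 of 27, early and meiotic germline genes in 20 of 26, spermatogenesis genes in 43 of 47, and all 16 major sperm protein genes and all 6 vitellogenins rose. Neuronal genes fell in 21 of 27 cases, pharynx genes in 8 of 9 and vulva and egg-laying genes in 9 of 15. All of these counts were the same adjusted over the list alone, and each list was enriched in its direction (largest adjusted p 0.0196, for vulva and egg-laying, Fisher's exact test). Of 25 dauer and stress resistance genes, 12 rose and 8 fell, the same adjusted over the list alone, and the list was not enriched in either direction (adjusted p = 0.177 and 0.79042). Among those that rose were the superoxide dismutase gene sod-3 (0.327 to 2.80 CPM), the glyoxylate enzyme gene icl-1 (95.8 to 584 CPM), the lysozyme gene lys-7 (0.804 to 104 CPM) and the metallothionein gene mtl-1 (0.449 to 6.50 CPM). Respiratory chain genes rose in 3 of 33 cases (5 with RLE size factors and 2 with library size only), among them nuo-5 (210 to 450 CPM), and DNA replication and cell cycle genes in 9 of 23, among them cyb-1 (20.4 to 327 CPM), both the same adjusted over the list alone. The last 3 hours fall on one part of the molting wave, so values of cuticle genes at hours 20 to 22 are those of that part.

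The later part of dauer exit was tested for the same 8 h wave as continuous development, at hours 11 to 22. Cuticle and molting genes again rose and fell. The molting gene mlt-10 had an amplitude of 3.19 ± 0.21 (SE, log2) with a peak at 17.5 h, dpy-7 2.97 ± 0.47 with a peak at 16.16 h, and the protease gene nas-37 2.56 ± 0.13 with a peak at 16.42 h. Among the widest waves were those of the cuticle genes col-63 (5.20 ± 0.57, peak at 17.5 h), bli-1 (4.93 ± 0.67, peak at 16.5 h) and rol-1 (4.68 ± 0.57, peak at 17.4 h). Among regulators, lin-42 (2.12 ± 0.32) peaked at 16.8 h, grh-1 (1.80 ± 0.21) at 16.8 h, bed-3 (2.56 ± 0.24) at 18.1 h and nhr-25 (0.95 ± 0.12) at 11.3 and 19.3 h, while nhr-23 passed narrowly (0.63 ± 0.19, adjusted p = 0.0481, edgeR). The myosin gene unc-54 (0.11 ± 0.07), ama-1 (0.08 ± 0.03), elt-2 (0.05 ± 0.09) and lin-28 (0.03 ± 0.04) did not pass the test.

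By edgeR's quasi-likelihood F-test with the thresholds used for continuous N2, 5025 of 15360 genes (32.7%) oscillated, with a median amplitude of 1.24 (quartiles 0.84 and 1.71). All 6 furrow collagens, all 14 other named cuticle collagens and all 24 molting and apical matrix genes oscillated, with 113 of 120 col collagens, 43 of 45 hedgehog-related genes such as grd-6 (4.40 ± 0.62), 25 of 30 astacin proteases such as nas-27 (3.23 ± 0.35), 19 of 26 patched-related genes such as ptr-17 (2.69 ± 0.13) and 17 of 19 abu and phat genes. These counts were the same adjusted over the list alone, and each list was enriched (largest adjusted p 0.00686, for furrow collagens, Fisher's exact test). Molting cycle regulators were called in 15 of 19 cases (16 adjusted over the list alone, adjusted p = 0.000345). Collagen processing genes (7 of 10, 8 adjusted over the list alone, adjusted p = 0.0826), heterochronic genes (8 of 13, 0.138), pharynx genes (6 of 9, 0.161) and seam cell genes (6 of 9, 0.161) were not enriched; their list-alone counts equal those over all genes except where given. Pharynx examples were myo-1 (0.79 ± 0.08, peak at 13.5 h) and tnt-4 (1.13 ± 0.13, peak at 13.1 h). Furrow collagens peaked on average 0.992 h before the other named cuticle collagens (16.18 and 17.17 h; two-sided exact permutation p = 0.00193).

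Sperm genes were also called in this window: 39 of 47 spermatogenesis genes and 14 of 16 major sperm protein genes, the same adjusted over the list alone, such as msp-142 (1.35 ± 0.29) and spe-19 (1.59 ± 0.43). With a quadratic instead of a linear trend 6 of these 53 stayed called, against 63.8% of the other 4972. The 12 hours hold 1.5 cycles, and the period is not well fixed by them. The total was 1076 genes at a period of 7 h, 5640 at 9 h and 6425 at 12 h. Over genes called at 8 h with an amplitude of at least 1, the median best period was 10.1 h (quartiles 9.1 and 11.7 h). Of these 3276 genes, 756 lay at an edge of the range searched. At 8 h the total was 2228 without a trend term and 3238 with all 22 hours and a spline trend.

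Whether both N2 courses shared one oscillation was asked next. Largely the same genes were called, in the same order. Of 15207 genes tested in both, 3965 oscillated in continuous development and 4979 in dauer exit, and 3468 did in both, where independent lists would share 1298 (odds ratio 44.9, 95% interval 40.2 to 50.1, Fisher's exact test). All 6 furrow collagens, 14 other named cuticle collagens, 24 molting and apical matrix genes, 19 patched-related genes and 16 abu and phat genes called in continuous N2 were called in both courses, as were 99 col collagens, 40 hedgehog-related genes, 23 astacin proteases and 14 molting cycle regulators. By contrast 12 major sperm protein genes were called in dauer exit alone and 1 in both, and 32 spermatogenesis genes in dauer exit alone and 6 in both. Peaks in dauer exit came 1.41 h later on the 8 h clock (mean resultant length 0.968; the highest of 1000 shuffles of the pairing was 0.0824), and 98.9% of the 3468 genes lay within 1 h of that shift. Amplitudes were higher in dauer exit for 72.3% of these genes, with a median ratio of 1.10 (quartiles 0.986 and 1.30). Both courses were fitted at 8 h. Over genes called with an amplitude of at least 1, the median best period was 8.4 h in continuous N2 and 10.1 h in dauer exit. The amplitudes at 8 h do not compare wave sizes if the periods differ.

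**Figure D4:**
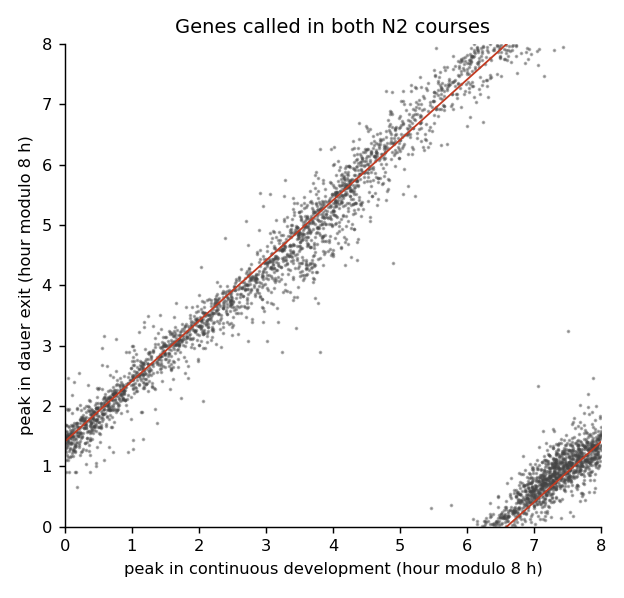
Fitted peak in dauer exit against that in continuous N2, in hours modulo 8 h, for each of the 3468 genes called in both courses; the line marks a shift of 1.41 h. Points lie along the line over the whole cycle.

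Whole library profiles matched in the same way. Over the 2163 genes with an amplitude of at least 1 in continuous N2, the dauer-exit library at 8 h was closest to continuous N2 at 23 h (Pearson's r across genes 0.90) and that at 18 h to 32 h (r = 0.92). The libraries at 1 to 5 h were all closest to 21 h, the earliest hour of continuous N2, with r of 0.52 to 0.64. Genes are not independent replicates, so these r values describe the libraries only.

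A joint fit then asked which genes had a different wave in the 2 courses after the 1.41 h shift. No gene passed: 0 of 15824 had an adjusted p under 0.05 by edgeR's quasi-likelihood F-test, with 877 at an unadjusted p under 0.05, and limma voom with a separate spread per course also gave 0, with 905 unadjusted. The smallest p-values were those of tdc-1, the tyrosine decarboxylase of tyramine synthesis (amplitude 0.59 in continuous N2 and 0.27 in dauer exit, adjusted p = 0.115), adh-1 (1.09 and 2.34), F18A12.7 (2.62 and 0.29), scvp-1 (0.71 and 1.87) and F58G6.3 (0.29 and 0.27), the last 4 with an adjusted p of 0.206. In simulated data the same fit recovered 24% of differences of 0.5 and 98% of differences of 2, so most differences of 0.5 would be missed. With the clock moved by 1 h more or 1 h less, 2192 or 1877 genes passed. The joint fit used 8 h for both courses, so a difference in cycle length was not tested.

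The third course followed glp-4(bn2) worms. The allele changes the protein, so the level of the gene's own transcript does not check the label, and germline genes do. Early and meiotic germline genes averaged a log2 CPM of 1.28 in glp-4, against 5.17 in continuous N2 and 5.29 in dauer exit. The germline helicase gene glh-1 lay between 32.3 and 48.1 CPM in glp-4. Oogenesis genes averaged -0.05 in glp-4, against 3.85 and 4.16, spermatogenesis genes -1.75, against 1.34 and 0.64, and DNA replication and cell cycle genes 3.64, against 5.66 and 5.73. Neuronal genes averaged 4.48, against 4.20 and 4.22, and body-wall muscle genes 10.15, against 9.85 and 7.76, while vitellogenins averaged 8.43, against 2.11 and 0.866. No test was made, since strain and age differ together and no N2 library has the same hours.

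**Figure D5:**
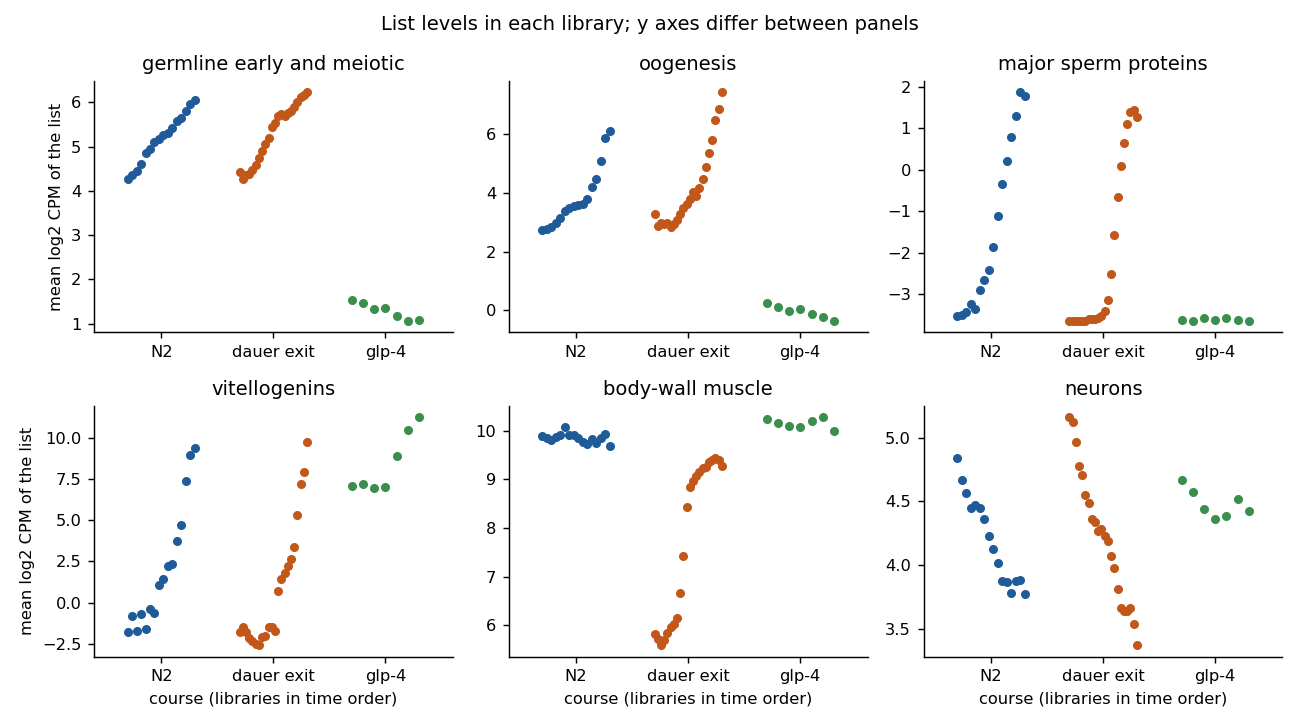
Mean log2 CPM of 6 gene lists in every library, with libraries of each course in time order from left to right and a separate y axis per panel. Early and meiotic germline genes average 1.28 in glp-4 and 5.17 in continuous N2, while neuronal genes average 4.48 and 4.20.

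Within the glp-4 course, adult cuticle and yolk genes rose. The adult collagen gene col-19 (WBGene00000608, chromosome X, 421707 to 422691, WBcel235) went from 2.86 ± 0.195 CPM (SD, hours 40 to 44, n = 3) to 2448 ± 1990 CPM (hours 48 to 52), with col-119 (2.13 to 1931 CPM), col-129 (8.78 to 4946 CPM) and col-140 (6.18 to 3028 CPM). Much of the end value of col-19 came from the 52 h library, at 4656 CPM, against at most 1897 CPM in any other. The yolk protein genes vit-2 (1644 to 9584 CPM), vit-6 (1611 to 12000 CPM) and vit-3 (5.47 to 139 CPM) rose as well. The astacin gene nas-22 had no counts in the first 3 libraries and 7.89 CPM in the last 3, at least 272-fold higher. In the other direction, col-176 fell from 1514 to 65.4 CPM, col-41 from 210 to 10.0 CPM, the cuticle gene dpy-6 from 266 to 16.12 CPM and the tubulin gene tba-8 from 3.72 to 0.242 CPM.

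The linear term passed in edgeR's quasi-likelihood test for 745 rising and 220 falling genes of 14407. Rising genes included 41 of 124 col collagens (62 adjusted over the list alone), 7 of 32 astacin proteases (15 adjusted over the list alone) and 3 of 6 vitellogenins (all 6 adjusted over the list alone), with adjusted p of 6.2e-21, 0.00596 and 0.0132 by Fisher's exact test. Of the 124 col collagens 8 fell (9 adjusted over the list alone, adjusted p = 0.00386). Hedgehog-related genes rose in 6 of 44 cases (7 adjusted over the list alone, adjusted p = 0.112), among them grd-14 (57.3 to 425 CPM) and grd-6 (43.3 to 221 CPM). Spermatogenesis genes rose in 3 of 19 cases (4 adjusted over the list alone, adjusted p = 0.271), among them spe-46 (0.324 to 3.23 CPM). Of 19 molting cycle regulators, the nuclear receptors nhr-25 (15.1 to 5.66 CPM) and nhr-85 (29.6 to 11.2 CPM) fell and the kinase gene nekl-2 (15.6 to 33.0 CPM) rose, the same counts adjusted over the list alone. The wave-like genes mlt-10 (177 to 289 CPM) and dpy-7 (147 to 40.4 CPM), and unc-54 (10158 to 8005 CPM), did not pass. The 20 body-wall muscle genes had a median fitted change of 0.02 (-0.12 with library size only).

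These counts rest on few libraries. Without the library at 40, 42, 44, 46, 48, 50 or 52 h, rising genes numbered 1085, 17, 127, 142, 54, 54 and 1734, and falling genes 410, 0, 13, 16, 0, 1 and 549, by edgeR. Where the count of falling genes was 0, without 42 or 48 h, 457 and 664 genes had an unadjusted p under 0.05 and a fitted fall of at least 1, and no other tool was run. With library size as the only scaling, 635 rose and 404 fell (61.1% rising, against 77.2%), and the median change over all genes was -0.14, against 0.01.

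The same course was tested for the 8 h wave. In the 12 hours sampled, mlt-10 ranged from 35.7 to 615 CPM, lin-42 from 16.37 to 357 CPM and nas-37 from 38.5 to 347 CPM. These genes were highest at 46 h, with lower values before and after. Such a course was not counted over the molting list. The fitted wave of mlt-10 had an amplitude of 1.03 ± 0.82, that of dpy-7 0.88 ± 0.72 and that of rol-6 0.87 ± 0.63. No gene passed: 0 of 14407 had an adjusted p under 0.05 by edgeR's quasi-likelihood F-test (549 at an unadjusted p under 0.05), DESeq2 called 180 and limma, on the log2 values the authors deposited, called 0. Adjusted over the list alone, 26 of 124 col collagens, 7 of 19 abu and phat genes and 5 of 32 astacin proteases passed.

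The genes that oscillated in continuous N2 had larger fitted amplitudes here than other genes. Over 3546 of them the median fitted amplitude was 0.49 in glp-4 and 1.17 in continuous N2, against 0.15 (0.14 to 0.16 over 1000 draws) for genes not called that were matched on expression. A fitted amplitude cannot be below 0 and grows with scatter (median SE 0.28 over the 3546 genes). The match did not cover scatter, which may account for part of the difference. The 8 h wave explained 36.6% of the detrended variance in glp-4 and 67.9% in continuous N2, and a 12 h wave 88.0% in glp-4. The amplitudes at 8 h therefore do not compare wave sizes if the periods differ. The fit left 3 residual degrees of freedom in glp-4 and 12 in continuous N2. Scatter alone then gives a larger explained share in glp-4, so 36.6 and 67.9% are not on one scale. The 36.6% does not by itself show an 8 h wave in glp-4. By list, over all members tested, median amplitudes in glp-4 were 1.14 for col collagens, 0.93 for furrow collagens, 0.91 for hedgehog-related genes and 0.83 for molting and apical matrix genes, against 0.13 for body-wall muscle, 0.12 for neurons and 0.05 for ribosomal protein genes. With the 8 h wave, the fitted peaks of the 3546 genes gathered around a shift of 6.46 h modulo 8 h from continuous N2. The mean resultant length was 0.831, against at most 0.0477 in 1000 shuffles. Of the genes 85.5% lay within 1 h of that shift, where random peaks would give 25%. The genes share the same libraries and are not independent, so these values describe the fits and do not test for one shift of the clock. The glp-4 libraries at 40, 46 and 52 h were closest to continuous N2 at 27, 31 and 36 h (Pearson's r across the 2163 genes with an amplitude of at least 1 there 0.76, 0.79 and 0.85), and 36 h is the last hour of that course. These matches did not keep one offset in hours. Over all 15622 genes, by Spearman's correlation, the libraries at 40 and 52 h were both closest to 21 h (0.95 and 0.86) and that at 46 h to 23 h (0.92), so the match in time depends on the genes used.

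A joint fit asked which genes had a different wave in glp-4 and continuous N2. Since no gene was called in both, each whole-hour shift of the glp-4 clock was tried, and counts ran from 5 genes at 6 h to 3672 at 2 h. The 5 genes at 6 h had a smaller fitted 8 h wave in glp-4: col-149 (amplitude 3.12 in continuous N2 and 1.08 in glp-4), C08F11.3 (2.0995 and 0.45), K02D3.2 (1.80 and 0.38), Y75B8A.28 (1.82 and 0.39) and ugt-5 (1.04 and 0.15), with adjusted p of 0.0110 for the first, 0.0188, 0.0461, 0.0110 and 0.0461 (edgeR's quasi-likelihood F-test). In simulated data this fit gave 204 false calls among 14022 genes, and limma voom with a separate spread per course called 1 gene.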

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

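Of the tests in this part, the fits of glp-4 at longer periods, the sets of 6 continuous N2 libraries and the search over clock shifts were chosen after the result was seen.

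In glp-4 the library at 52 h lay apart from the other 6 on 10 of 53 measures, by the gap to its nearest neighbour relative to the whole range. The cut-off marks about 1 in 20 groups of unordered values by chance. That rate does not apply here, since the libraries are in time order and the measures are not independent. A trend that steepens would also set the last library apart. Dauer and stress resistance genes averaged a log2 CPM of 5.80 there, against 5.09 to 5.28 in the others, heterochronic genes 4.56 (5.41 to 5.90), vulva and egg-laying genes 2.096 (2.51 to 2.73) and housekeeping controls 6.23 (6.64 to 6.77). The superoxide dismutase gene sod-3 was at 24.3 CPM (3.07 to 5.09), the adult collagen gene col-19 at 4656 CPM (2.68 to 1897), the heterochronic gene lin-28 at 21.0 CPM (11.6 to 14.9), the germline helicase gene glh-1 at 32.3 CPM (43.7 to 48.1), the glyoxylate enzyme gene icl-1 at 458 CPM (827 to 1077) and the body-wall myosin gene unc-54 at 4592 CPM (9344 to 11075). The 10 most abundant genes took 8.85% of the counts of this library. No explanation was tested.

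The 5 genes whose fitted 8 h wave was smaller in glp-4 than in continuous N2, led by the collagen gene col-149, were the least number over the 8 clock shifts tried. Of 40 splits of the same 23 libraries into courses, 2 gave at least 5 genes, the real one included, so chance cannot be excluded. The other such split gave 111 genes, many times the real count, which a structure of these libraries other than the courses or false calls of the fit (204 in simulated data) may give; what sets that split apart was not tested. For both N2 courses the real count was 0 by edgeR (877 at an unadjusted p under 0.05, and 0 by limma voom); all 40 splits then give as many by construction, which says nothing of chance, and the highest of the others was 7.

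No gene passed edgeR's test of an 8 h wave in glp-4 (549 at an unadjusted p under 0.05), while DESeq2 called 180 and limma 0. The genes mlt-10, lin-42 and nas-37 were highest at 46 h, with lower values before and after. The number of libraries alone is argued against only for waves with the size and scatter of continuous N2. Sets of 7 continuous N2 libraries taken 2 h apart gave a median of 1485 called genes, although the set from 24 to 36 h gave 512. For smaller waves the number of libraries stays open. In simulated glp-4 data the fit recovered 0, 2, 28 and 58% of waves with amplitudes 0.5, 1, 1.5 and 2. The last library stays open: without it 0 genes were called by edgeR, but 2280 then had an unadjusted p under 0.05, against 222 to 781 without any other library, and 3 of 26 sets of 6 continuous N2 libraries also gave 0 (2193 to 3180 unadjusted), so a count of 0 from 6 libraries does not exclude it. A cycle longer than 8 h stays open too, since a 12 h wave was called for 3057 genes in glp-4, but a 12 h wave cannot be told from one rise and fall within 12 h. A slower or weaker oscillation in the mutant, or another growth temperature, which is not given in the sources used here, may account for it, and a larger scatter of the libraries (median SE of the amplitude 0.28 over the genes called in continuous N2) was not excluded.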

How the results depend on the processing

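The alternatives without hours 34 to 36 or without hours 50 and 52, library size only, the periods of 10 and 12 h and the separate spread per course were chosen after the results were seen. Of the main counts under the planned and added alternatives, 56 stayed within 1.5 times the main count and 26 did not; of the values of named genes 3276 kept their side of the threshold, 281 no longer passed and 38 newly passed, and none reversed. Genes oscillating in continuous N2 (4116) numbered 2163 with an amplitude of 1 and 2086 at a period of 7 h. In dauer exit (5025) they numbered 3087 with an adjusted p under 0.01, 3276 with an amplitude of 1, 1076 at 7 h, 2228 with no trend and 3238 over all 22 hours with a spline. In glp-4 (0 by edgeR, 549 at an unadjusted p under 0.05) there were 180 by DESeq2, 69 at a period of 9 h, 521 at 10 h, 3057 at 12 h, 20 with a quadratic trend and 120 without hours 50 and 52. Rising genes in glp-4 (745) numbered 1667 by DESeq2, 103 with an adjusted p under 0.01 and 1665 without hours 50 and 52, of which 521 were among the 745. Falling genes there (220) numbered 404 with library size only, 687 by DESeq2, 443 in the authors' normalized table, 6 with an adjusted p under 0.01 and 658 without hours 50 and 52, of which 150 were among the 220. Genes with a different wave numbered 2192 and 1877 with the clock shifted 1 h more or less between N2 courses (0), and 79 and 1077 between continuous N2 and glp-4 (5), with 1 under a separate spread per course. Without hours 50 and 52 the glp-4 fit has 5 libraries for 4 coefficients, so its counts carry little weight. Stricter thresholds lower counts by construction; for the other settings the cause was not tested.

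Leaving out each library in turn, 6035 values of named genes kept their side of the threshold, 253 no longer passed and 10 newly passed. It gave 3676 to 4249 oscillating genes in continuous N2, 4070 to 5051 in dauer exit and 0 to 0 in glp-4 (edgeR, 222 to 2280 at an unadjusted p under 0.05). Rising genes ran from 3046 to 3232 and falling genes from 2206 to 2408 in continuous N2, from 4619 to 4839 and from 3663 to 4124 over dauer exit, and from 17 to 1734 and from 0 to 549 in glp-4, where the 42 h library gave both low ends and the 52 h library both high ends. No paired analysis was possible because replicate numbers only name libraries in accession order and no time point has a replicate. Depth was at least 18512549 counts and limits only genes of low expression. Residuals of neighbouring libraries were more alike than independent scatter would give in all 3 courses (median correlation 0.0876 against -0.263 in continuous N2, -0.0397 against -0.389 in dauer exit and -0.135 against -0.556 in glp-4), so the p-values of all 3 are somewhat too small.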

Other observations

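Of the tests in this part, the overlap of sperm genes with continuous N2 and both tests of the 9 h period were chosen after the results were seen.

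The share of counts taken by translation and tissue genes differed between the first and last libraries of the courses. Ribosomal protein genes took 20.3% of counts in the first 3 libraries of dauer exit and 12.7% in the last 3, against 17.6 and 13.1% in continuous N2 and 11.7 and 8.44% in glp-4. Neuronal genes took 0.286 and 0.0674% in dauer exit, and 0.129 and 0.110% in glp-4. Vitellogenins took 0.420 and 2.63% in glp-4. The mean log2 CPM of intestine genes was 6.55 at hours 1 to 3 of dauer exit and 7.53 at hours 20 to 22, and that of respiratory chain genes was 7.49 and 8.18. These are values without a test.

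The order of libraries within a course was shuffled 40 times, the real order included. In every test only the real order (1 of 40) gave as many genes, so the counts depend on the order of the libraries. Shuffling breaks any smooth change over the course together with the 8 h wave. It therefore does not show that the oscillation calls come from a wave. In continuous N2 the real order gave 4116 oscillating genes, against at most 2509 in the others, and 5613 rising or falling genes, against at most 1. In dauer exit it gave 5025 oscillating genes, against at most 1171, and 8721 rising or falling genes, against at most 2863. In glp-4 it gave 965 rising or falling genes, against at most 670.

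Sperm genes were called oscillating in dauer exit, where spermatogenesis and major sperm protein genes came on late. Of the 53 called sperm genes, 13.2% were called in continuous N2 too. This share cannot decide whether they have a repeating wave, since a missing call is not a difference. The joint fit called 0 of 15824 genes as different between the N2 courses. Major sperm protein genes also averaged a log2 CPM of only -3.48 in the first 3 libraries of continuous N2. A repeating wave therefore stays open. One late switch-on fitted by an 8 h wave may account for most of the calls in dauer exit: with a quadratic trend 11.3% stayed called, against 63.8% of the other called genes. Later hours, which would show whether the genes fall again, were not analysed here.

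More genes were called at 9 h than at 8 h in continuous N2 (4557 and 4116). Over genes already called at 8 h with an amplitude of at least 1, the lower quartile of the best period was 8.1 h. In that set, a best period above 8 h was therefore not limited to a few genes. Genes called at 9 h but not at 8 h are not in it, so this cannot decide whether a few genes with a long cycle give the excess. Distortion by the linear trend term stays open, since without it 2935 genes were called at 9 h and 2999 at 8 h, although 8.5 h then gave the most calls (3081), and with a quadratic trend the counts at 9 and 8 h were 4296 and 3979, climbing to 4736 at 12 h. A cycle slightly longer than 8 h in these worms, which per the labels grew slowly, may account for it as well; growth rate itself was not tested.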
